A study of Mus musculus with 6 samples.

How the data were processed

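RNA was measured in 6 libraries of tumour cells from mice bearing 2208L, a transplantable mouse mammary tumour grown in Balb/c mice. The group called CTC held 3 libraries of circulating tumour cells that had been propagated from peripheral blood, and the group called PT held 3 libraries of tumour cells enriched after the primary tumour was dissociated. Per the labels, the blood and the tumours came from matched mice, and the replicate number was taken from the same label as the group. Per the labels' protocols, total RNA was column-purified and 100 ng entered an mRNA sequencing library kit. Nothing states whether the kit or the counting kept the strand, so overlapping and antisense genes could not be told apart.

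The authors deposited 1 table of raw read counts per Ensembl gene, with whole numbers for 54532 genes in 6 columns, and a gene length in bases for each gene. Per the submitters' processing notes, HISAT2 was used and the builds GRCm38 and mm10 were named. The version of the aligner, the read counter and the annotation release are not given in the sources used here. Of the 54409 genes also in GENCODE M21, an annotation of GRCm38, 53499 (98.3%) had the same start and end, and coordinates are given as in the deposited table. Every entry named a gene.

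Total counts ranged from 23845953 to 27897320 per library, and 3 counts corresponded to between 0.108 and 0.126 CPM (counts scaled to a common library total). This floor covers counting error only, because reads without molecular identifiers are not independent molecules. No pair of libraries came near sampling noise: the chi-square per degree of freedom between libraries was at least 90.4, so every library was counted as 1 sample.

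The count test was the quasi-likelihood test of edgeR (version 4.0.16, R version 4.3.3), with glmQLFit and glmQLFTest on the deposited counts, TMM normalization and the default filterByExpr filter by group. The filter left 13874 genes, of which 12019 were protein-coding. P-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05, and log2 fold changes are CTC minus PT. Standard errors were derived from the F statistic. Log2 CPM used a prior count of 2, and means ± SD are TMM-scaled CPM unless a count is named. Whether CTC and PT lay apart in all libraries was counted per gene, for which chance alone gives 10%.

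Before the data were examined, 43 lists of genes were fixed, 14 of them markers of host cell types. The 28 lists with at least 5 tested genes were tested with camera (limma version 3.58.1) at a preset correlation of 0.01 between genes, adjusted over the lists; the other 15 lists were described by counts. The camera test was repeated with an estimated correlation and the lists were also tested with fry.

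The rule for naming genes was fixed at the same time. It took the 10 largest changes each way among protein-coding genes past the threshold, with an average log2 CPM of at least 3 and no overlap between groups. It also took up to 3 members per list in the list's direction and up to 2 against it, and a fixed set of tumour, cytokine and host cell genes. As no gene passed in edgeR, the first part was applied, after this was seen, to the genes that passed in DESeq2 (version 1.42.0), where 28 genes met it (13 higher and 15 lower in CTC); 1 of the genes it took is not reported here. For the second part, the direction of a list was that of the camera test, since no list had a called member.

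The labels place same-numbered libraries in the same mouse, so the numbers pair the samples. The main test, with its standard errors and intervals, did not use this pairing, and a fit with a replicate block was an alternative. Across genes, the deviations of same-numbered libraries from their group means correlated at -0.015, 0.157 and 0.298 for replicates 1, 2 and 3, with a mean of 0.147 against -0.0706 for libraries of different numbers. Because each group was centred on its own mean, the second mean follows almost entirely from the first and is no separate comparison. Of the 6 ways to pair the libraries, 2 gave a mean as high as the labelled pairing. Genes are not independent replicates, so these correlations carry no p-value.

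Alternatives fixed before the data were examined were a replicate block, a gene length correction with and without that block, RLE and upper-quartile scaling, DESeq2, limma-voom, no filter, a filter of 1 CPM in 3 libraries, protein-coding genes only, marker genes left out of library sizes, lists without shared genes, and leaving out each library or each matched pair. A GC correction with and without a length correction and the block, DESeq2 with the block, and a filter of 10 counts over all libraries were added after seeing the data. Corrections removed each library's lowess trend (span 0.4) on gene length or on the median GC content of the gene's GENCODE M21 transcripts. A GC value was lacking for 12 tested genes.

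The edgeR, DESeq2, limma-voom, camera and fry tests were tested on simulated data for the comparison of CTC with PT, drawn for 13874 genes. The counts used the real means, the real library sizes and the dispersion trend, not each gene's own dispersion. A random spread around the trend raised the average dispersion. For the gene tests, 200 changed genes in each of 5 runs were drawn only from genes above a minimum expression level. In that simulation edgeR called 0% of genes changed 2-fold, 7.16% of those changed 4-fold and 42.7% of those changed 8-fold, with 7 unchanged genes called over all runs. DESeq2 called 8.06%, 55.2% and 90.0% of them, with 360 unchanged genes called over all runs, 72 per run. limma-voom called 0%, 7.46% and 37.9%, with 8 unchanged genes called. A list shifted as a whole was called by camera at the preset correlation in 5 of 5 runs. Camera with an estimated correlation called it in 2 and fry in 4, and none of the 3 called any other list. The shift was equal in all members of that list, the hypoxia and glycolysis list. It was larger in size than the list's real median and mean log2 fold changes of -0.346 and -0.574. Smaller or uneven shifts of a list were not simulated. The simulated genes varied independently of each other, which the members of a real list need not do.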

Results

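Expression was measured by RNA sequencing in tumour cells of the 2208L mouse mammary tumour, in 3 libraries of circulating tumour cells propagated from blood (CTC) and 3 libraries of tumour cells enriched from the dissociated primary tumour (PT). Library totals were 27897320, 24496217 and 23951093 counts for CTC replicates 1, 2 and 3, and 27371166, 23845953 and 23874946 counts for PT replicates 1, 2 and 3. CTC cells were propagated and PT cells were not described as propagated, so handling and group could not be separated. The comparison asked how tumour cells recovered from blood differed from those of the primary tumour of the matched mice.

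Epithelial genes were highly expressed in both groups. Krt8, a simple epithelial keratin, was at 1692 ± 704 CPM in CTC and 2301 ± 633 CPM in PT (SD, n = 3 each). Epcam, an epithelial adhesion molecule, was at 236.5 ± 62.4 and 272.8 ± 76.9 CPM, and Cdh1, which encodes E-cadherin, was at 317.2 ± 217 and 187.0 ± 46.3 CPM. The mesenchymal genes Vim (vimentin) and Fn1 (fibronectin) were expressed beside them. Vim was at 545.4 ± 73.2 CPM in CTC and at 285.7 ± 317 CPM in PT, where single libraries ranged from 26.9 to 639.8 CPM. Fn1 was at 1210 ± 517 and 1399 ± 852 CPM. The transcription factors Snai2 and Zeb1, which repress epithelial genes, reached at most 2.20 and 7.42 CPM in any library. None of these 7 genes passed the edgeR quasi-likelihood test, and their smallest adjusted p was 0.736. The tumour suppressor gene Trp53 had between 1537 and 2758 counts per library. Counts per gene do not show whether its transcript was intact or gave a working protein. The proliferation gene Mki67 was at 197.7 ± 118 CPM in CTC and 232.4 ± 126 CPM in PT.

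Transcripts of host cells were scarce in both groups, apart from genes of the fibroblast and adipocyte lists in some libraries. Ptprc, the common leukocyte antigen CD45, had 12 counts over all 6 libraries, and Ly6g and Adgre1, markers of neutrophils and macrophages, had 0, for which 3 counts (at most 0.126 CPM per library) is the upper limit. The 12 pan-leukocyte genes summed to between 2.17 and 16.7 CPM per library, the neutrophil genes to between 1.94 and 29.4 CPM and the endothelial genes to between 7.62 and 54.4 CPM. Most of the highest neutrophil sum, in CTC replicate 3, came from S100a8 with 647 counts, while its partner S100a9 had 13. The macrophage and monocyte genes summed to 11.7, 23.5 and 7.47 CPM in CTC replicates 1, 2 and 3 and to 6.03, 6.16 and 1.72 CPM in PT replicates 1, 2 and 3, higher in each CTC library. Csf1r, with 157, 488 and 5 counts in CTC and 2, 32 and 2 in PT, and Cd68, with 26 to 127 counts per library, made up most of the sums in CTC, while Lyz2 had at most 1 count per library and C1qa 0. The dendritic cell genes summed to 9.10, 11 and 7.52 CPM in CTC and to 13.3, 16.1 and 14.8 CPM in PT, lower in each CTC library, mostly from Zbtb46 and Batf3. Of the 14 host cell lists no other separated the groups, and chance separates 10%. The fibroblast genes summed to 221 ± 286 CPM in CTC (9.61, 107 and 546 CPM in replicates 1, 2 and 3). In PT they summed to 239 ± 308 CPM (593, 28 and 96.3 CPM). Col1a1, the main collagen gene of fibroblasts, had at most 44 counts in any library. Other members were higher, with Col6a3 at 545.1 CPM in PT replicate 1 and 344.9 CPM in CTC replicate 3, and Col3a1 at 124.6 CPM in CTC replicate 3. The cells that expressed them were not tested. The adipocyte genes reached 413 CPM in CTC replicate 3 and at most 5.27 CPM elsewhere. The remaining host cell lists stayed at or below 58.7 CPM in every library.

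**Figure D1:**
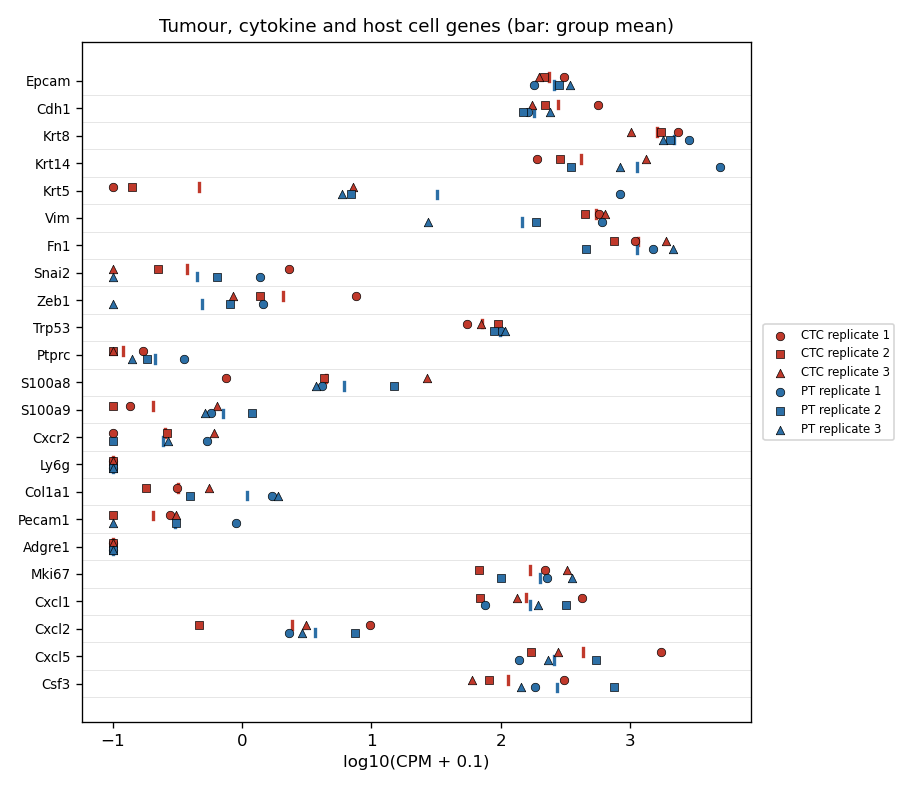
Expression of the 23 tumour, cytokine and host cell genes of the fixed set, as log10 of CPM plus 0.1, with 1 symbol per library (red for CTC, blue for PT, shape for replicate) and a bar at each group's mean of the plotted values. Epcam, Krt8 and Cxcl5 lie far above Ptprc, Ly6g and Adgre1 in all 6 libraries.

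No single gene separated the groups beyond the spread between libraries in the main test. Of 13874 genes, edgeR called 0 higher and 0 lower in CTC, with a smallest adjusted p of 0.611. At an unadjusted p under 0.05 it gave 460 higher and 459 lower, together 919, where chance alone gives 693.7. Other splits of the 6 libraries into 3 and 3 gave from 148 to 1941 genes, so this excess does not mark the real grouping. limma-voom also called 0 genes, and edgeR with the replicate block called 0, with a smallest adjusted p of 0.199. DESeq2 called 40 genes higher and 47 lower in CTC, 87 in all, each by at least 2-fold, and with the replicate block 119 higher and 134 lower, 71 of the 87 among them. Without a filter on low counts edgeR called 121 higher and 78 lower. CTC lay above PT in all libraries for 825 genes and below for 855, together 12.1% of genes against 10% by chance. Among genes with a mean log2 CPM over 3, the median SD within groups was 0.408 on the log2 scale. The median absolute difference between the group means was 0.301 for the same genes. The first describes single libraries and the second means of 3 libraries, so their sizes cannot be compared directly. In simulated counts of 13874 genes in this design, DESeq2 called 72 unchanged genes per run (0.527%). Its calls of changed genes were 5.4 at 2-fold, 37 at 4-fold and 59.4 at 8-fold per run. Such calls let more unchanged genes past the adjustment. Of its 87 real calls, 75 lay among the 13874 genes. False calls were thus common in the simulation, but no run without changed genes was made. Their share of the real list without the block is therefore not known. Matched libraries were not simulated, so the share of false calls among its 253 calls with the block is not known.

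The genes that DESeq2 placed higher in CTC included Myh10, Lama3 and Antxr2. Myh10, the heavy chain of non-muscle myosin IIB (ENSMUSG00000020900, chromosome 11, 68691559 to 68816632, GRCm38), was at 123.0 ± 53.7 CPM in CTC and 17.9 ± 8.58 CPM in PT (SD, n = 3 each). Its log2 fold change was 2.78 (SE 0.50, 95% interval 1.63 to 3.94). The adjusted p was 0.726 in edgeR, 0.235 in edgeR with the replicate block and 0.000203 in DESeq2. Lama3, the alpha 3 chain of laminin-332, was at 141.4 ± 120 CPM against 26.5 ± 8.37 CPM, and Antxr2, a cell surface receptor for matrix proteins, at 40.8 ± 9.40 against 8.23 ± 4.30 CPM. The cytokine gene Il24 was at 47.8 ± 39.0 against 10.6 ± 0.15 CPM, and Abcc4, an efflux transporter, at 21.5 ± 10.9 against 5.16 ± 1.78 CPM. Prl2c2, a proliferin gene, was at 245.0 ± 255 against 21.7 ± 18.3 CPM, a level made uncertain by near-identical gene copies. It was at 530.9 CPM in CTC replicate 1 but at 41.7 CPM in CTC replicate 2, next to 41.3 CPM in PT replicate 1, and its log2 fold change of 3.49 was 2.23 without CTC replicate 1 and 4.35 without PT replicate 1. B4galt5, a galactosyltransferase, was at 109.6 ± 56.7 against 22.5 ± 2.92 CPM. It lies on chromosome 2 between 166 and 170.5 Mb, where neighbouring genes were also higher in CTC replicate 3, with a median deviation of 1.54 on the log2 scale, and between 166.9 and 168 Mb, where they were lower in CTC replicate 1 (-0.77). Mmd, Faxc and Crip2 completed the 10, with log2 fold changes of 2.37, 2.24 and 2.05. Without CTC replicate 1 those of Lama3 and Il24 were 1.51 and 1.32, from 2.42 and 2.18, without PT replicate 2 that of Mmd was 3.00, and without PT replicate 1 that of Crip2 was 2.77.

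The genes that DESeq2 placed lower in CTC included Shf, Pgf and Id4. Shf, an SH2 domain adaptor (ENSMUSG00000033256, chromosome 2, 122348892 to 122369162, GRCm38), was at 15.5 ± 15.7 CPM in CTC and 172.7 ± 59.8 CPM in PT, a log2 fold change of -3.48 (SE 0.77, 95% interval -5.25 to -1.71) with an adjusted p of 0.726 in edgeR and 9e-05 in DESeq2. Pgf, placental growth factor of the VEGF family, was at 4.96 ± 3.08 against 28.1 ± 4.65 CPM, and Nrtn, which encodes neurturin, at 12.7 ± 13.0 against 71.2 ± 32.7 CPM. Id4, an inhibitor of helix-loop-helix transcription factors, was at 38.1 ± 35.7 against 187.2 ± 71.9 CPM. Trib3, a pseudokinase induced in amino acid stress, was at 35.4 ± 9.03 against 168.0 ± 81.7 CPM. Syne4, a nuclear envelope protein, was nearly constant in CTC at 3.91 ± 0.11 CPM against 21.2 ± 9.36 CPM. Tspan11, Ncmap and Hid1 had log2 fold changes of -3.23, -2.67 and -2.19. Without CTC replicate 3 those of Shf, Tspan11, Pgf, Nrtn and Id4 were -4.73, -3.84, -3.09, -3.74 and -3.40, from -3.48, -3.23, -2.50, -2.48 and -2.29. Tspan11 was the only 1 of the 19 genes named here that DESeq2 did not call with the replicate block (adjusted p = 0.275).

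**Figure D2:**
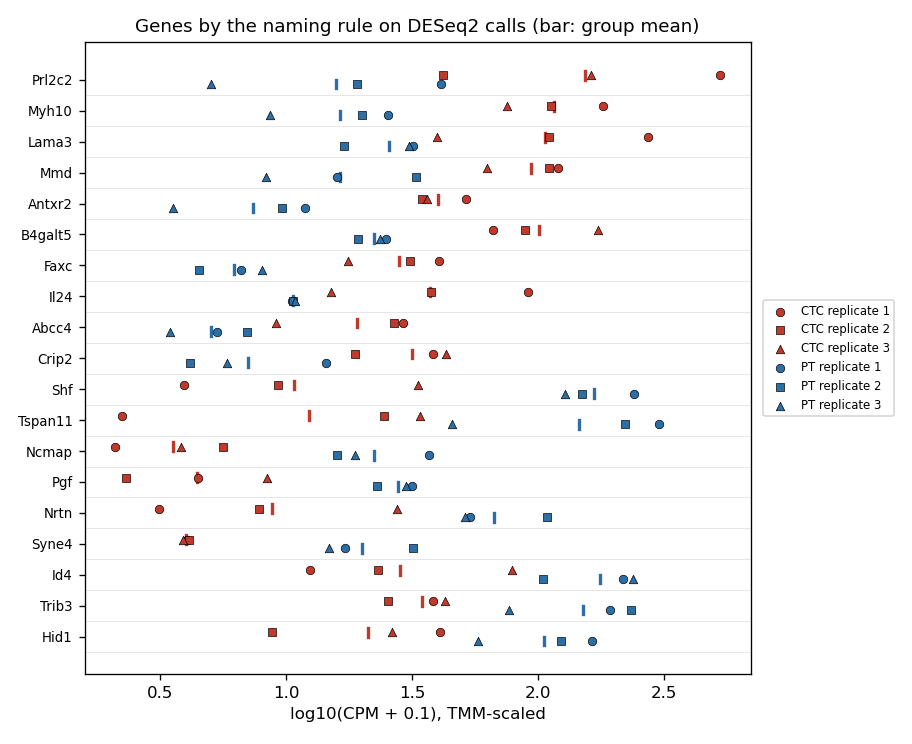
The 19 genes named from the DESeq2 calls, as log10 of TMM-scaled CPM plus 0.1, with 1 symbol per library (red for CTC, blue for PT, shape for replicate) and a bar at each group's mean of the plotted values. The groups do not overlap for any of the 19, a condition of the naming rule, and Syne4 shows the narrowest spread within CTC (SD 0.11 CPM).

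Genes of glycolysis, respiration, amino acid metabolism, DNA replication and ribosomes were lower in CTC as lists at the preset correlation. The library medians of the groups overlapped for each of the 5. In the hypoxia and glycolysis list, 19 of 23 tested genes were lower in CTC, with a median log2 fold change of -0.35 (camera adjusted p = 0.000635; adjusted p = 0.631 with an estimated correlation). The glycolytic enzyme genes Tpi1, Aldoa and Gpi1 were at 737.5 ± 201, 852.9 ± 216 and 325.1 ± 80.5 CPM in CTC and at 1691 ± 665, 1820 ± 856 and 601.4 ± 195 CPM in PT, without overlap. Pfkfb3, which promotes glycolysis, went the other way at 42.4 ± 4.93 against 29.2 ± 4.12 CPM. In the amino acid and integrated stress response list 16 of 20 genes were lower (median -0.45, adjusted p = 0.00116; adjusted p = 0.631 with an estimated correlation). Psat1, of serine synthesis, was at 376.8 ± 68.3 against 683.7 ± 80.9 CPM, and Trib3 passed when adjusted over the list alone. In the DNA replication list 19 of 22 genes were lower (median -0.31, adjusted p = 0.00567; adjusted p = 0.631 with an estimated correlation). Its member E2f1, a transcription factor of the S phase, was at 61.4 ± 8.74 against 98.0 ± 3.11 CPM. In the ribosomal protein list 17 of 20 genes were lower (median -0.24, adjusted p = 0.00567; adjusted p = 0.631 with an estimated correlation). In the oxidative phosphorylation list 20 of 24 were lower (median -0.24, adjusted p = 0.0229; adjusted p = 0.631 with an estimated correlation), with Uqcrc1 of complex III at 236.9 ± 64.4 against 447.9 ± 180 CPM. No member of these lists passed over all genes tested. By library, PT replicate 3 had the lowest median deviation for the amino acid list (-0.516, with 10 of 20 members lowest there). For glycolysis it lay at -0.104, below CTC replicates 2 (-0.1) and 3 (-0.007). CTC replicate 2 lay above PT replicate 2 for DNA replication (0.11 against 0.066). It also lay above PT replicate 3 for ribosomal proteins (0.18 against -0.01) and respiration (0.123 against 0.058). The glycolysis call was the only one of the 5 kept without each library in turn, though it ended without replicate 1 of both groups (adjusted p = 0.236). The amino acid call ended without PT replicate 2 (adjusted p = 0.127). The DNA replication call ended without CTC replicate 3 (0.161) or PT replicate 3 (0.224), the ribosomal call without CTC replicate 1 (0.167) or PT replicate 2 (0.127), and the respiration call without CTC replicate 1 (0.284), CTC replicate 3 (0.0964) or PT replicate 2 (0.127). Without replicate 1 of both groups the ribosomal and respiration calls ended (0.0932 and 0.176), without replicate 2 of both the amino acid call (0.279), and without replicate 3 of both the DNA replication and respiration calls (0.566 and 0.135). With a gene length correction the ribosomal and respiration calls also ended (0.0644 and 0.118), with a ribosomal median of -0.096. Without CTC replicate 1 the ribosomal and respiration medians were -0.088 and -0.10, without CTC replicate 2 they were -0.38 and -0.38 and that of DNA replication -0.46, without PT replicate 2 the ribosomal median was -0.16, and without PT replicate 3 the glycolysis median was -0.63.

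TGF-beta targets, basement membrane genes and interferon response genes were higher in CTC as lists. Of 15 TGF-beta targets, 12 were higher, with a median log2 fold change of 0.36 (camera adjusted p = 0.00293; adjusted p = 0.55 with an estimated correlation). Ltbp1, which binds latent TGF-beta, was at 70.8 ± 14.0 CPM in CTC and 22.3 ± 4.10 CPM in PT, and passed when adjusted over the list alone and in DESeq2 (adjusted p = 0.0175). Id3 was at 123.7 ± 38.2 against 66.0 ± 13.6 CPM, while Tgfbi stayed at or below 1.20 CPM in all libraries. The TGF-beta median was 0.55 without CTC replicate 2 and 0.70 without PT replicate 3. Its call was kept in 26 of 28 alternatives and was lost with an estimated correlation and with fry. Of 11 basement membrane genes, 8 were higher (median 0.26, adjusted p = 0.00595; adjusted p = 0.631 with an estimated correlation). Lama3 and Lamb1 led, and Lamb1 was at 372.8 ± 219 against 165.3 ± 70.1 CPM, in a run of chromosome 12 genes that were lower in PT replicate 1 (median deviation -0.74). The collagen IV gene Col4a2 ranged from 0.12 to 732.1 CPM within PT. The basement membrane call ended without CTC replicate 1 (adjusted p = 0.132), without PT replicate 2 (0.127, where the median was -0.096) and without genes shared with other lists (0.064). Its median was 0.40 without CTC replicate 2 or CTC replicate 3, 0.93 without PT replicate 1 and 0.59 without PT replicate 3. It was 0.094 with a gene length correction (adjusted p = 0.0423), 0.62 with a GC correction, 0.82 with the replicate block, 0.77 in DESeq2, 0.82 in limma-voom and 0.88 without a filter on low counts, and 0.060 without replicate 2 of both groups, where the call ended (0.0505). All 24 interferon response genes had a positive log2 fold change, with a median of 2.25 (adjusted p = 6.7e-06; adjusted p = 0.631 with an estimated correlation). This rested on CTC replicate 3, where 23 of the 24 were highest: the antiviral gene Bst2 was at 579.8 CPM there and at most 117.9 CPM elsewhere, and Ifi44 at 159.0 and at most 6.39 CPM (in CTC replicate 1, where its neighbours on chromosome 3 were also higher, with a median deviation of 0.67). Without CTC replicate 3 the interferon median was -0.049 and the call was lost (adjusted p = 0.851). With the replicate block the median was 1.02 (adjusted p = 0.00411), in DESeq2 with the block 0.96, and with the block and a GC and gene length correction 0.93.

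**Figure D3:**
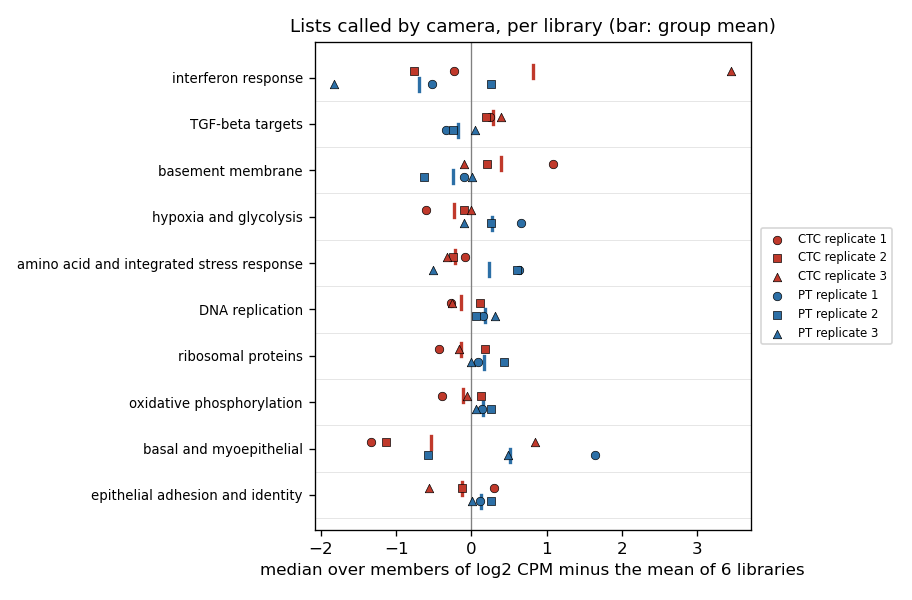
The 10 lists called by camera, each shown as the median over its members of log2 CPM minus the mean of the 6 libraries, with 1 symbol per library (red for CTC, blue for PT, shape for replicate) and a bar at each group's mean. CTC replicate 3 stands at 3.44 for the interferon response list, and for the glycolysis list CTC replicate 1 is lowest at -0.61 and PT replicate 1 highest at 0.66.

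Epithelial and basal lists were lower in CTC with adjusted p-values just under the threshold. Of 25 epithelial adhesion and identity genes, 16 were lower (median log2 fold change -0.22, camera adjusted p = 0.049; adjusted p = 0.631 with an estimated correlation). Ovol2, a repressor of mesenchymal genes, was at 5.10 ± 0.90 CPM in CTC and 13.9 ± 3.97 CPM in PT, and passed only in DESeq2 with the replicate block (adjusted p = 0.023). The epithelial protease gene Prss8 and its inhibitor Spint2 were at 23.3 ± 2.04 against 52.5 ± 16.3 and 241.8 ± 31.1 against 426.5 ± 77.2 CPM. Cldn4, a tight junction claudin, was at 282.3 ± 214 against 112.1 ± 53.7 CPM. Of 15 basal and myoepithelial genes, 10 were lower (median -1.01, adjusted p = 0.0458; adjusted p = 0.631 with an estimated correlation). Krt5 and Krt14, keratins of basal cells, were highest in PT replicate 1 at 876.2 and 5266 CPM, while Krt5 was at most 6.996 CPM in the other 5 libraries. With the replicate block the epithelial adjusted p was 0.1, so that 6 and not 7 lists were lower, and the basal list stayed called (0.0113). The epithelial call ended without CTC replicate 2 (0.112), CTC replicate 3 (0.764), PT replicate 2 (0.208) or PT replicate 3 (0.058), and the basal call without CTC replicate 1 (0.27), CTC replicate 2 (0.253), PT replicate 1 (0.724) or PT replicate 3 (0.123). The epithelial median was -0.067 without CTC replicate 3 and -0.43 without CTC replicate 1. With a GC correction the epithelial shift was nearly gone (median -0.024, adjusted p = 0.333), and it was -0.077 with a GC and gene length correction (adjusted p = 0.4) and -0.10 with a gene length correction (adjusted p = 0.0991). The basal median was -0.047 without PT replicate 1, -0.39 without CTC replicate 1 and -3.16 without CTC replicate 3. It was -0.45 in DESeq2 (adjusted p = 0.604), -0.40 without a filter on low counts (0.29) and -1.68 in limma-voom (0.0413), and the basal call also ended with a GC correction (0.0874). Of 28 alternatives, 6 kept the epithelial call and 12 the basal call. The mesenchymal and EMT list was not called, with 13 of 21 genes higher and an adjusted p of 0.353, but it was called higher without PT replicate 1 (adjusted p = 0.00753, median 0.80) and without replicate 1 of both groups (7e-06). Within it Zeb2 was at 10.6 ± 2.72 against 4.69 ± 0.99 CPM and the membrane protease gene Mmp14 at 147.1 ± 44.6 against 87.5 ± 6.49 CPM, both without overlap.

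Genes of cytokines that recruit neutrophils were expressed in both groups and varied more between libraries than between groups. Cxcl5, a neutrophil chemokine, was at 721.4 ± 873 CPM in CTC and 312.3 ± 220 CPM in PT, with the highest value, 1728 CPM, in CTC replicate 1. Cxcl1 was at 206.3 ± 191 and 200.9 ± 125 CPM, and Cxcl2 at 4.30 ± 4.81 and 4.21 ± 2.90 CPM. Csf3, which encodes the granulocyte growth factor G-CSF, was at 149.0 ± 138 and 368.7 ± 349 CPM, with the highest value, 770.9 CPM, in PT replicate 2. The 95% interval of its log2 fold change ran from -3.20 to 0.59. The cytokine list was not called: 13 of 15 genes were higher in CTC, with a median of 1.08 and an adjusted p of 0.218 (median 0.56 and adjusted p = 0.409 with the replicate block). Its direction rested on CTC replicate 1, without which the median was -0.69 (adjusted p = 0.271), and without replicate 1 of both groups the list was called lower (0.000621, median -1.27). It was called higher without CTC replicate 2 (0.0197), without PT replicate 2 (0.00581), without replicate 2 of both groups (6.85e-05) and in DESeq2 (0.00154). NF-kB targets were not called either (adjusted p = 0.317), except without CTC replicate 3 (0.0298) and in DESeq2 (0.0177), with 10 of 14 higher, Tnfaip3 at 137.0 ± 151 against 35.4 ± 22.0 CPM, and Bcl3 at 23.1 ± 3.35 against 56.3 ± 13.5 CPM, the latter passing when adjusted over the list alone and in DESeq2 with the replicate block (adjusted p = 0.039).

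In all, 10 of 28 lists were called, 3 higher and 7 lower in CTC, and 0 of the 439 genes tested over all 28 lists passed in edgeR. Adjusted over the list alone, Ltbp1, Trib3 and Bcl3 passed and no other member did. With an estimated correlation 0 lists were called, and with the directional test of fry 0. The fry test for members changed in either direction gave TGF-beta targets an adjusted p of 0.0148, and the other lists 0.307 or more. The 18 lists not called had adjusted p-values from 0.124 to 0.886. Among them, the mitosis list had a median of 0.092 with 13 of 20 genes higher, which was between 0.039 and 0.059 without CTC replicate 1, 2 or 3 or PT replicate 1 or 2 and -0.059 with a GC correction. For p53 targets it was 0.53 with 12 of 15 higher (adjusted p = 0.124, but 0.0394 in DESeq2 and 0.0459 with its replicate block), and 0.29 without CTC replicate 1 (0.27). Matrix proteases had a median of 0.58 with 12 of 14 higher (adjusted p = 0.182, but 0.00994 in DESeq2), which was -0.0020 without CTC replicate 1, 0.38 without CTC replicate 3 and 0.30 with the replicate block. Plau, the urokinase gene of the protease list, was at 212.4 ± 227 CPM in CTC and 37.7 ± 10.5 CPM in PT. It passed in DESeq2 (adjusted p = 0.0352, and 0.176 with the replicate block). The groups overlapped for Plau, with 470.2 CPM in CTC replicate 1 but 40.49 CPM in CTC replicate 3, below PT replicate 3 at 47.47 CPM. Its log2 fold change of 2.495 fell as low as 0.966 among the alternatives. The p53 target Mdm2 was at 69.4 ± 34.0 against 30.3 ± 9.41 CPM. It lies on chromosome 10 in runs of neighbouring genes with median deviations of 0.90 in CTC replicate 1, -0.73 in PT replicate 1 and -0.66 in PT replicate 3. Genes of immediate early response and dissociation, a sign of tissue handling, had a median of -0.16 with 13 of 20 lower in CTC (adjusted p = 0.131). This list was called lower without CTC replicate 3 (0.0481), without replicate 3 of both groups (0.0256) and in DESeq2 with the replicate block (0.0459), and its adjusted p reached 0.936 with a GC and gene length correction (median -0.023). For Wnt targets the median was 0.35 although the test pointed lower, and it had no stable sign, at 0.013 without CTC replicate 1, 0.18 without CTC replicate 2, -0.12 without PT replicate 1, 0.23 without PT replicate 3 and -0.41 in DESeq2. For iron and ferroptosis genes the median was 0.11 although the test pointed lower, and it was -0.096 without CTC replicate 1, 0.35 without CTC replicate 2, -0.11 without CTC replicate 3, 0.20 without PT replicate 2 and -0.017 with a gene length correction.

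The libraries did not fall into the 2 groups along the main axis of variation. The first principal component, with 43.6% of the variance, placed CTC replicates 1 and 2 at -111.3 and -51.9 and CTC replicate 3 at 52.8, beside PT replicate 3 at 66.1. CTC replicate 3 correlated most with PT replicate 3 across genes (r = 0.9425) and CTC replicate 2 most with PT replicate 2 (0.9369), while CTC replicate 1 correlated most with CTC replicate 2 (0.9316). Each library also had its own trend on GC content, with Spearman correlations across genes of -0.425, 0.215 and -0.348 in CTC replicates 1, 2 and 3 and 0.592, 0.22 and -0.269 in PT replicates 1, 2 and 3. Genes are not independent replicates, and these correlations describe the libraries only.

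**Figure D4:**
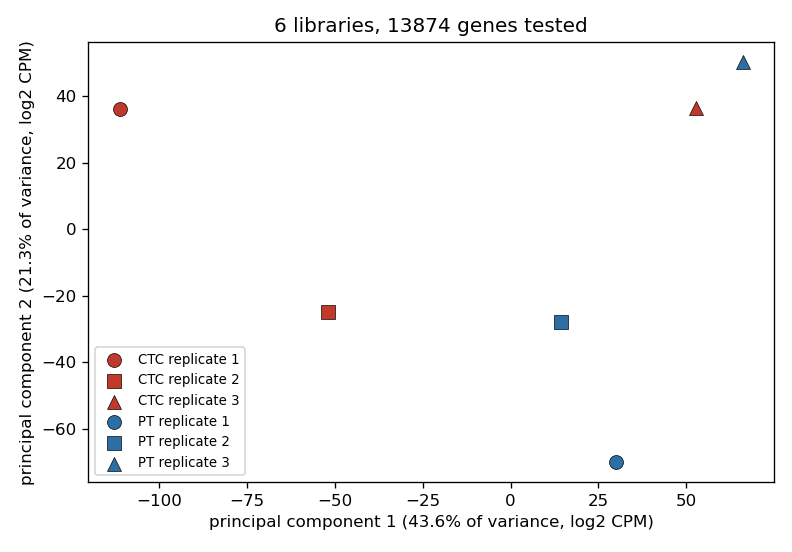
The 6 libraries on the first 2 principal components of log2 CPM over the genes tested, with the share of variance on each axis (red for CTC, blue for PT, shape for replicate). CTC replicates 1 and 2 lie left of 0 on the first component, and CTC replicate 3 lies at 52.8 beside PT replicate 3.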

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

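The GC corrections, the filter of 10 counts over all libraries and DESeq2 with the replicate block were chosen after seeing the data. With edgeR, 0 genes passed in either direction with the replicate block, with each other scaling, with gene length or GC corrections, with stricter filters, and without each library or matched pair, where 374 to 1891 genes had an unadjusted p under 0.05; limma-voom called 0 (920 unadjusted). Exceptions were no filter on low counts, with 121 genes higher and 78 lower (147 of these 199 among the genes tested with the filter), and DESeq2, with 40 and 47, or 119 and 134 with the block; the counts at 2-fold or more were identical in each. Without the filter the prior degrees of freedom of edgeR were 34.7 against 3.85, and with a filter of 10 counts over all libraries they were 4.69 and 0 genes passed. Of the DESeq2 calls, 71 were shared between its fits. List members passing numbered 4 in DESeq2, 10 with its block and 21 without the filter.

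The count of lists called higher was 3, from 2 to 5 without single libraries and up to 7 without replicate 1 of both groups, and was 8 in DESeq2, 0 with an estimated correlation and 0 with fry. The count called lower was 7, ranging from 4 to 7 without single libraries or pairs, and was 4 with a gene length correction, 4 with that correction and the replicate block, 0 with an estimated correlation and 0 with fry. The causes were not tested. With the replicate block alone the lists numbered 3 higher and 6 lower, 0 genes passed, and the loss of the epithelial list was the only changed call among the lists called, while the interferon and basement membrane medians moved from 2.25 and 0.26 to 1.02 and 0.82. The interferon list had medians from -0.049 (without CTC replicate 3) to 2.97 (without PT replicate 2) without single libraries, and -0.23 without replicate 3 of both groups, and the basal list a median of 0.30 without replicate 1 of both groups. Of lists not called, MHC class I was called higher without CTC replicate 2 (adjusted p = 0.0197), replicate 1 of both groups (0.00551) or replicate 2 of both groups (0.0341) and lower without replicate 3 of both groups (0.00996), cholesterol synthesis higher without CTC replicate 3 (0.00522), the unfolded protein response lower with a GC correction (0.0416), and fibrillar collagens lower without CTC replicate 3 (0.0171), PT replicate 2 (0.00351) or replicate 2 of both groups (0.000395), with no filter (0.0337) and with the filter of 10 counts (0.046), and higher without replicate 1 of both groups (0.000621). Fibroblast genes were called higher without replicate 1 of both groups (0.049) and lower without replicate 2 of both groups (0.039). The mean correlation of matched libraries stayed between 0.1 and 0.17. Of 163 genes named by the rule, 43 changed sign in some alternative, none past the threshold. The scaling alternatives moved the median log2 fold change of all genes from 0.053 to at least 0.023, under 0.1. With a chi-square per degree of freedom of at least 90.4 between libraries, differences between libraries were far above counting error, and genes under 0.126 CPM could not be compared.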

Other observations

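The tests of leukocyte RNA, of GC content and gene length, and of other splits in edgeR were chosen only after the results were seen; those of shuffled gene order, held-out genes and other splits in DESeq2 and camera were fixed before. Several abundant genes differed between libraries of the same group by far more than between groups; they were chosen after their values were seen. Xist, the RNA that silences an X chromosome, had 9, 356 and 14308 counts in CTC replicates 1, 2 and 3 and 4378, 3683 and 5 counts in PT replicates 1, 2 and 3, while 4 Y-linked genes had at most 1 count together in any library. Over 278 X-linked genes the median deviation from the mean of all libraries stayed between -0.07 and 0.04 on the log2 scale. Hp, which encodes haptoglobin, had 8, 10700 and 22942 counts in CTC replicates 1, 2 and 3 and 905, 69522 and 29744 counts in PT replicates 1, 2 and 3. Ptgs2, the inducible cyclooxygenase, was at 1258 CPM in CTC replicate 1 and at most 142.4 CPM elsewhere, and Fabp4, a fatty acid binding protein of adipocytes, at 346.6 CPM in CTC replicate 3 and at most 2.19 CPM elsewhere, with Adipoq at 0 counts in that library. The collagen IV genes Col4a1 and Col4a2, neighbours on chromosome 8, each had 3 counts in PT replicate 3 and 997 or more in every other library.

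The fibroblast growth factor receptor gene Fgfr1 (chromosome 8, 25513654 to 25575718, GRCm38) was at 23.1, 108.7 and 498.7 CPM in CTC replicates 1, 2 and 3 and at 1090, 714.4 and 1237 CPM in PT replicates 1, 2 and 3. The groups did not overlap, and it did not pass in edgeR (adjusted p = 0.726; 0.762 with the replicate block) or DESeq2 (0.136), but passed in DESeq2 with the replicate block (0.000692). It lies in a run of 73 genes on chromosome 8, from 11.5 to 31.16 Mb, that were higher in PT replicate 3 (median deviation 0.72), the library with its highest value.

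The interferon response genes were high in CTC replicate 3, with a median deviation of 3.44 against at most 0.25 in any other library. RNA from leukocytes was argued against, since the pan-leukocyte genes summed to 2.17 CPM there, the lowest of the 6 libraries, and up to 16.7 CPM elsewhere, with Ptprc at 0 counts. The neutrophil sum was the highest of the 6 there (29.4 CPM), but with 647 counts of S100a8 against 13 of S100a9 and 0 of Ly6g. The B cell sum, also the highest, was 0.919 CPM. Endothelial, skeletal muscle and adipocyte sums were the highest too (54.4, 7.77 and 413 CPM), so RNA from those cells stays open. Of the 9891 adipocyte counts in CTC replicate 3, however, 8861 came from Fabp4, with Plin4 at 935, Cidec at 35 and Adipoq at 0 counts. A trend on GC content and gene length was also argued against, since the median was 3.41 after its removal. PT replicate 3, the tumour matched by its label, had the lowest median deviation of the 6 libraries (-1.82, with 12 of 24 members lowest there). The rise was thus not shared by the primary tumour cells of that mouse, as far as 1 library shows. No biological explanation was tested. A response of the tumour cells in that culture, or of the circulating cells but not the primary tumour in that mouse, stays open.

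The hypoxia and glycolysis genes were lower in CTC, with a median log2 fold change of -0.35. After a GC correction the list stayed called (adjusted p = 0.000676, median -0.39), and after a gene length correction too (adjusted p = 0.000434, median -0.39), which argues against either trend as the whole cause. The call was lost with an estimated correlation, and without replicate 1 of both groups (adjusted p = 0.236). Propagation of the CTC cells and their origin from blood cannot be told apart by this design, and neither was tested.

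Runs of neighbouring genes, sought in each library by itself, were shifted together. With GC and length trends removed, 18 runs of at least 10 genes had a running median (31 genes) beyond 0.6 on the log2 scale. Without that correction there were 27 runs. The strongest were chromosome 2 from 166 to 170.5 Mb in CTC replicate 3 (23 genes, median 1.54), the X chromosome from 150.8 to 166.9 Mb in CTC replicate 2 (45 genes, 1.30) and chromosome 10 from 108.2 to 127.3 Mb in CTC replicate 1 (62 genes, 0.90). Some places were shifted in more than 1 library. Runs within the chromosome 10 stretch were lower in PT replicates 1 (-0.73) and 3 (-0.66), and a run within the chromosome 2 stretch was lower in CTC replicate 1 (-0.77). Shuffling the gene order 100 times gave at most 0 runs, which argues against chance order, and the 18 runs left after the correction argue against GC content and gene length as the whole cause. Copy number differences between the tumour cells are a candidate explanation: in runs defined on every other gene, 90.3% of 279 held-out genes lay on the run's side, with a median shift of 0.69. Neighbouring genes regulated together would also give this and stay open, since no DNA was analysed here.

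The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. In edgeR the real split called 0 genes and the other splits at most 0. With 0 real calls, 10 of 10 had to give as many, so this count cannot tell the real split from the others. At an unadjusted p under 0.05 the real split gave 919 genes in edgeR. Other splits gave 976, 1103 and 1941 genes, and the rest gave fewer than the real one. In DESeq2 the real split called 87 genes and the highest other split 326, with 4 of 10 giving as many. For lists the real split called 10 and the highest other 13, with 5 of 10 giving as many. The split that gave 326 genes set CTC replicates 1 and 2 with PT replicate 2 against the rest, several times the real count, which points to a structure of the samples along their main axis of variation. Among the splits that part all 3 matched pairs, as the real one does, the others called 92, 17 and 39 genes in DESeq2 and 11, 13 and 10 lists.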
